A study of Mus musculus with 8 samples.

How the data were processed

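The series measured DNA methylation and RNA in stable clones of NIH3T3, an immortalised mouse embryo fibroblast line. Clones carried either an expression plasmid for FLAG-tagged 14-3-3ε, a member of the family of proteins that bind phosphorylated partners, or the control vector, and were kept in medium with 10% serum under 800 µg/mL of the selection drug G418, per the labels' protocols. Control clones 2 and 3 and 14-3-3ε clones 10 and 12 were each measured by reduced representation bisulfite sequencing (RRBS), which reads CpG-rich fragments after bisulfite conversion, and by RNA-seq. This made 8 samples in 4 groups of 2. RRBS libraries started from 1 µg of DNA and kept fragments of 150 to 400 bp, per the labels' protocols. RNA libraries had inserts of about 200 bp.

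Each assay was analysed here from 1 table of the authors' own comparison, with no value per library. Reads were trimmed with Trim Galore, aligned to mouse build mm10 with Bismark, Bowtie2 and TopHat2, counted with HTSeq and compared with methylKit and DESeq2, per the submitters' processing notes, which name these tools without version, role or setting. In the RNA-seq table the mean level is a signal that the authors deposited under a header that DESeq2 uses for the mean over libraries of counts divided by size factors. It was read so here and is called the mean normalized count, though the file itself does not state how it was made. The fold change and its standard error are on the log2 scale, as deposited by the authors. Their values stay small in genes with few reads: among 2386 genes with a mean normalized count above 0 and at most 1, the largest size was 0.11 in the authors' deposited table. That is how moderated estimates behave, so folds of weakly expressed genes are understated. The test statistic is a score that the authors deposited, equal to the fold change over its standard error. P-values and adjusted p-values were deposited by the authors for 17478 and 11482 of 24062 listed genes. An adjusted p was given down to a mean normalized count of 33.1, and Benjamini-Hochberg adjustment over those 11482 genes returned the deposited values to within 2.18e-15. In the RRBS table the authors deposited, for each cytosine, a p-value, a q-value and a difference in percent methylation in percentage points, per the file headers.

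The direction of neither comparison is stated in the files. Positive values were taken as higher in 14-3-3ε clones than in control clones, the usual convention of both tools, and every direction given here rests on that reading. Coverage, coverage limits and the handling of the 2 clones per group in the methylation test are not given in the sources used here. If reads were pooled within groups, the q-values measure read sampling in these clones and not the spread between clones. Depth per sample is unknown from these tables, so no counting interval is given.

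The RRBS table held 2361933 lines. A total of 253 exact duplicate lines, all on unplaced contigs, were removed, which left 2361680 cytosines. Those with q under 0.05 were called higher or lower by the sign of the difference. Cytosines were averaged without weights over fixed windows of 1 kb and over gene-end windows. A gene-end window spans 1000 bp on each side of the annotated end of a gene that had more listed cytosines, because the gene table used (RefSeq genes of GRCm38.p6, the assembly of mm10) has no strand column, so such a window need not hold the transcription start. A window was called when it had at least 5 listed cytosines, at least 3 called cytosines, none called in the other direction, and calls at 10% or more of its cytosines. This rule replaces the planned count model and was chosen after seeing the data. To measure how far calls cluster, differences and q-values were shuffled 100 times among cytosines of the same chromosome and local density, and windows were called again. After seeing the data this was repeated with both strands of a CpG moved together. The gene table gives neither exons nor introns, so positions are given relative to whole genes. Of the 24062 symbols in the RNA-seq table, 22547 matched a current symbol and 1351 a single synonym.

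Genes were called at the authors' adjusted p under 0.05. The 23 gene lists were fixed before the data were examined. Each list with at least 3 tested members was tested with cameraPR of limma 3.58.1 on the authors' statistic with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 21 lists. No correlation could be estimated, since that needs values per library. Where members of a list move together more than the preset allows, its adjusted p is too small. Called members are counted over all genes and adjusted over the list alone. As planned, called members of either direction were also tested against the other tested genes with two-sided Fisher exact tests, adjusted over 23 lists. On gene-end calls, higher and lower calls were tested apart with two-sided Fisher exact tests, adjusted over both directions of all lists together. The relation between gene-end difference and log2 fold change was measured across genes by Spearman's rho, with 100000 permutations for all genes and 10000 for subsets, adjusted over 8 sets. Genes are not independent replicates. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

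Genes were named by a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among genes with adjusted p under 0.05 and a mean normalized count of 50 or more; Ywhae and Dnmt1; up to 4 called members per list by smallest adjusted p; the 8 regions per direction with the largest difference among those called; called gene ends of list members; and up to 8 genes per combination of directions among those called in both assays. The planned condition that regions move alike in every pair of clones could not be applied. A few genes that this rule selects are not reported here. Other members are named as examples of a list and were chosen after their values were seen.

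The steps were tested on simulated data. With fold changes drawn for 200 of 11482 genes at the authors' standard errors, 71.5% of 2-fold and 100% of 4-fold changes were called, with 2.05% and 2.44% of the calls false. All 20 shifted gene lists of the simulation were called, with the shift set in advance and noise drawn independently for each gene. Of 200 windows lowered among 3786 windows of chromosome 19, 99.5% were called lower. Coverage is unknown, so the q-values of lowered windows were set directly and not computed from reads. This share therefore checks the calling steps and not the power to find real changes. The gene simulation took the authors' standard errors as given, with independent normal noise, so a low share of false calls was built in. Its fold changes were not moderated, so recovery of real changes may be overstated. Its shares do not measure spread between clones.

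Planned steps that need counts or levels per library could not be used. These were the count models, methylation levels per library, coverage limits, the pooled test, read weighting, strand-aware promoters and leaving out each clone. Alternatives that were run covered thresholds, filters, window sizes, strands, list tests and chromosome centring.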

Results

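DNA methylation and RNA were compared between NIH3T3 fibroblast clones with a FLAG-tagged 14-3-3ε plasmid and clones with the control vector, with 2 clones per group in each of the assays. The design asked how methylation and transcript profiles differ in clones made to overexpress 14-3-3ε. The RRBS table listed 2361680 cytosines and 24062 genes stood in that of RNA-seq, of which 11482 had an adjusted p-value. Both tables hold the authors' comparison and no value per clone, so no spread between clones can be shown. Higher and lower refer to clones labelled 14-3-3ε relative to clones labelled control, a reading of the sign that neither table states. Positions are in build mm10.

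The level of the mouse gene for 14-3-3ε did not check this reading, and a higher level was not seen. This gene, Ywhae, lies on chromosome 11 from 75732887 to 75765841 and had a log2 fold change of -0.03 with a standard error of 0.18 and an adjusted p of 0.942 in the authors' deposited table. None of the 7 tested members of the 14-3-3 family passed the test, over all genes or adjusted over the list alone. The family ranged from -0.03 for Ywhae to 0.22 for Ywhaz in the authors' deposited table, and its list test gave an adjusted p of 0.727 with cameraPR. How transgene transcripts entered the counts is not given in the sources used here.

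In the comparison of expression, genes of the fibroblast matrix, proteases that remodel it, interferon-stimulated genes, homeobox regulators and the Dlk1 to Meg3 imprinted cluster were higher in 14-3-3ε clones, and cell cycle genes, those of the Mcm helicase among them, were lower. The chemokine gene Cxcl12, whose product attracts cells that carry the receptor Cxcr4, rose most, about 103-fold, with a log2 fold change of 6.68, a standard error of 0.33 and an adjusted p of 1.33e-89 in the authors' deposited table. The largest fall was that of Prl2c2, a proliferin gene, with a log2 fold change of -4.13, a standard error of 0.30 and an adjusted p of 9.27e-40 in the authors' deposited table. Of 11482 tested genes, 706 rose and 544 fell at an adjusted p under 0.05, and 331 of those that rose and 122 of those that fell changed at least 2-fold. These directions rest on the assumed sign. The standard errors, read as DESeq2 makes them, hold spread between clones. Even so, 2 clones per group separate differences between clones only weakly from an effect of 14-3-3ε.

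Next to Cxcl12, the 12 largest rises held genes of several kinds. Prelp and Optc, neighbouring genes on chromosome 1 for small leucine-rich proteoglycans, rose with log2 fold changes of 4.01 and 3.87 in the authors' deposited table. The fibrillar collagen gene Col3a1 rose by 3.25 (standard error 0.35), the microfibril gene Mfap5 by 3.12 (0.30) and the gene of the extracellular chaperone clusterin, Clu, by 3.02 (0.27) on the log2 scale of the authors' deposited table. Agtr2, the type 2 angiotensin II receptor gene, rose by 4.27 (0.30), and Stra6, a retinol uptake receptor gene, by 2.84 (0.39) in the same units of the authors' deposited table. Log2 fold changes in the authors' deposited table were 3.28 for the transcription factor gene Klf12, 2.93 for the X-linked gene Plac1, 2.70 for the interferon-inducible gene Ifi205 and 2.69 for the transcriptional repressor gene Hic1. The adjusted p of these 12 genes was at most 8.65e-10 in the authors' deposited table. Ifi205 belongs to a family of similar genes, so its reads are uncertain.

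Next to Prl2c2, the 12 largest falls were also in genes of several kinds. Ptx3, a pentraxin of innate immunity, fell by 3.11 on the log2 scale of the authors' deposited table, with a standard error of 0.35. The gene for the aryl hydrocarbon receptor, Ahr, fell by 2.43 (standard error 0.36) and Aldh3a1, an aldehyde dehydrogenase gene that this receptor can induce, fell by 2.45 (0.40) in the authors' deposited table. The nuclear receptor gene Nr1h5 fell by 2.24, the corneodesmosin gene Cdsn fell by 2.22 and the activin-binding gene Fst fell by 1.99 in the authors' deposited table. Mfng, a Notch-modifying glycosyltransferase gene, fell by 1.98, the receptor accessory gene Ramp3 fell by 1.91, the EGF receptor ligand gene Ereg fell by 1.85 and the AP-1 gene Fosl1 fell by 1.81 in the authors' deposited table. The adjusted p of these 12 genes was at most 2.82e-05 in the authors' deposited table. Prl2c2 has near-identical family members and Prl2c3, Prl2c5 and others were listed with mean normalized counts of about 1 or less in the authors' deposited table, so how reads were split among them is uncertain.

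Among genes of collagens and matrix, 17 of 32 tested members rose and none fell, and adjusted over the list alone 18 rose and 1 fell. The list test gave an adjusted p of 8.20e-12 with cameraPR. Beside Col3a1, log2 fold changes in the authors' deposited table were 1.73 for Col5a3, 1.11 for the crosslinking enzyme gene Loxl1 and 1.30 for Col6a1. The chief fibroblast collagen genes Col1a1 and Col1a2 rose by 0.98 and 0.89 on the log2 scale of the authors' deposited table. Of 26 extracellular proteases and inhibitors, 11 rose and 1 fell, 12 and 1 adjusted over the list alone, with an adjusted p of 3.30e-05 in the cameraPR test. Adamts4, Adamts2 and Mmp19 rose by 1.98, 1.93 and 1.61, while the urokinase receptor gene Plaur fell by 1.37 on the log2 scale of the authors' deposited table.

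Of 36 tested cell cycle genes, 1 rose and 11 fell, and adjusted over the list alone 2 rose and 16 fell. The list test gave an adjusted p of 5.29e-06 with cameraPR. All 6 genes of the Mcm2 to Mcm7 helicase, which unwinds DNA at replication, fell, with log2 fold changes from -1.03 for Mcm3 to -0.70 for Mcm2 in the authors' deposited table. The cyclin D1 gene Ccnd1 fell by 0.89 (standard error 0.17) and the replication clamp gene Pcna fell by 0.84 (0.22), while the CDK inhibitor gene Cdkn2c rose by 0.83 (0.22) in the authors' deposited table. The mitotic genes Aurka and Bub1b and the cyclin A2 gene Ccna2 fell as well, by 0.78, 0.73 and 0.79 on the log2 scale of the authors' deposited table.

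Of 27 interferon-stimulated genes, 9 rose and none fell, and 11 rose adjusted over the list alone. CameraPR gave the list an adjusted p of 7.85e-07. Gbp2, a guanylate-binding protein gene, rose by 2.33, the oligoadenylate synthetase-like gene Oasl2 by 2.08, Ifi27 by 1.24 and the transcription factor gene Stat2 by 1.22 on the log2 scale of the authors' deposited table. Of 40 homeobox and Polycomb target regulators, 11 rose and none fell, 14 and 1 adjusted over the list alone, with an adjusted p of 0.000278 with cameraPR. Of the 11, 3 lay in the Hoxd cluster and 2 each in the Hoxc and Hoxa clusters. They are therefore not independent, and the preset correlation may be too low for them. The same limit holds for the other lists, whose members may also move together. Hoxd3, Hoxd4 and Hoxd8, close together on chromosome 2, rose by 1.79, 1.54 and 1.11, and Osr1 by 0.90 on the log2 scale of the authors' deposited table. The annotated span of Hoxd4 lies within that of Hoxd3, so how reads were split between them is uncertain. Of 20 imprinted genes, 4 rose and none fell, 5 and none adjusted over the list alone, with an adjusted p of 0.00119 with cameraPR. These were Rian, Mirg, Meg3 and Dlk1, all on chromosome 12, with log2 fold changes of 1.70, 1.58, 1.42 and 0.90 in the authors' deposited table. All 4 belong to 1 cluster, and the imprinted list did not pass Fisher's exact test of called members (adjusted p 0.396), which the other 5 lists called with cameraPR passed.

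Among genes that write, remove or read DNA methylation, 2 of 22 rose and 1 fell, with equal counts adjusted over the list alone, and the list did not pass the cameraPR test (adjusted p 0.813). Dnmt1, the maintenance methyltransferase gene, had a log2 fold change of -0.45 with a standard error of 0.27 and an adjusted p of 0.309 in the authors' deposited table. Hells, a chromatin remodeller that aids maintenance methylation, fell by 1.09 (standard error 0.20) in the authors' deposited table. The gene of the 5-methylcytosine oxidase Tet1 and that of the methyl-CpG binding protein Zbtb4 rose by 0.74 (0.23) and 0.73 (0.25) on the log2 scale of the authors' deposited table.

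Feedback genes of Ras and growth signalling moved both ways, with 8 of 26 higher and 4 lower (8 and 8 adjusted over the list alone; cameraPR adjusted p 0.147, with a negative median and a positive mean). Counted in either direction, called members were more frequent than among other genes (odds ratio 7.07, Fisher exact adjusted p 4.53e-05). Spry1, Egr2 and Egr1 rose by 2.25, 2.14 and 1.77, and the chromatin gene Hmga2 fell by 1.19 on the log2 scale of the authors' deposited table. Chemokines and cytokines gave 5 rises and 3 falls of 27, also adjusted over the list alone (cameraPR adjusted p 0.0772). Their odds ratio for a call in either direction was 3.46 (Fisher exact adjusted p 0.0212). Beside Cxcl12 and Ereg, Hgf rose by 1.21 and Ccl11 by 1.93 on the log2 scale of the authors' deposited table. Contractile and myofibroblast genes gave 3 rises and 1 fall of 21 on both counts, over all genes and adjusted over the list alone, with Mylk at 1.46, Myl9 at 1.03, Cald1 at 0.59 and Des at -1.28 in the authors' deposited table. Their cameraPR adjusted p was 0.0805, and a rank-sum test gave an adjusted p of 0.0245. Integrin and adhesion genes gave 5 rises and 1 fall of 23 on both counts, over all genes and adjusted over the list alone, with Itga11 at 1.87 and Itgb7 at -1.50 in the authors' deposited table (cameraPR adjusted p 0.275). Of 19 genes of the epithelial-mesenchymal transition, 3 rose and 1 fell, also adjusted over the list alone (cameraPR adjusted p 0.449). These were Tgfbr2, Tgfb3 and Zeb1 at 1.39, 0.90 and 0.61 and Foxc2 at -1.48 in the authors' deposited table.

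Of 14 Yap/Taz targets 1 rose and 2 fell, 1 and 3 adjusted over the list alone (cameraPR adjusted p 0.105), with Ctgf at -1.76, Cyr61 at -0.93 and Amotl2 at 0.61 in the authors' deposited table. Of 21 p53 targets 1 rose and 2 fell, also adjusted over the list alone (cameraPR adjusted p 0.147), with Ckap2 at -1.21, Gtse1 at -0.83 and Sesn1 at 0.84 in the authors' deposited table. Few members of the lists for other lineages were tested: 6 for bone and cartilage (2 rose; 3 and 1 fall adjusted over the list alone), 5 for adipocytes (1 rose), 4 for muscle (2 fell), 4 for the germline (1 rose and 1 fell; 1 and 2 adjusted over the list alone), 4 for blood cells (none called), 3 for epithelium (1 fell), 2 for neural and glial cells (1 fell) and 1 for endothelium (not called). For adipocytes, muscle, blood, epithelium, neural cells and endothelium the count adjusted over the list alone was the same. Members called in these lists included Ogn at 1.41, Sox9 at 0.86, Brdt at 1.37, Taf7l at -1.09, Tnnt2 at -1.68, Krt14 at -1.41 and Map2 at -1.36 on the log2 scale of the authors' deposited table. The cameraPR adjusted p was 0.275 for bone and cartilage and for muscle, 0.727 for adipocytes and epithelium, 0.779 for the germline and 0.622 for blood, and the neural and endothelial lists were too small to test.

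**Figure D1:**
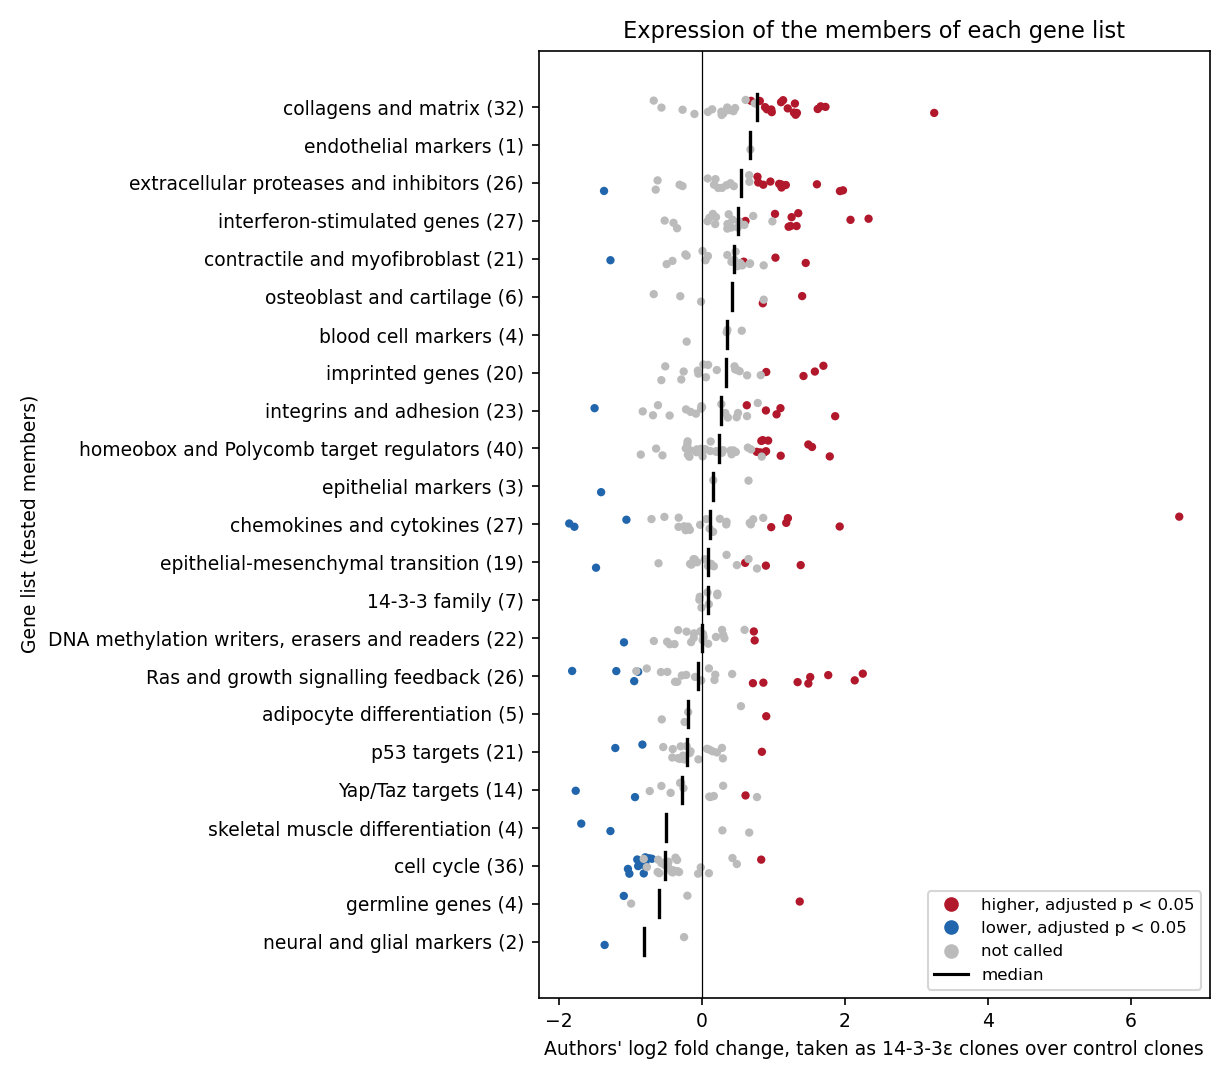
Authors' log2 fold change (horizontal axis, taken as 14-3-3ε clones over control clones) of each tested member of 23 gene lists (rows, with the number of tested members). Red points rose and blue points fell at an adjusted p under 0.05, grey points were not called, and black lines are list medians; 17 of 32 collagen and matrix genes are red and 11 of 36 cell cycle genes are blue.

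In the comparison of methylation at single cytosines, more positions were lower than higher in 14-3-3ε clones, in the assumed direction. Of 2361680 cytosines, 112032 were called at q under 0.05 (4.74%), 66777 lower and 45255 higher, a ratio of 1.48, from the q-values of the authors' deposited table. The 25th and 75th percentiles of the difference were -26.4 and -13.9 percentage points for lower cytosines and 13.3 and 25.6 for higher ones in the authors' deposited table. The mean over all cytosines was -0.491 points and the median 0 in the authors' deposited table, while the mean size of a difference, regardless of sign, was 4.96 points. With a difference of at least 25 points required as well, 19607 were lower and 12122 higher. The q-values do not show how far clones of a group differ.

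Lower calls outnumbered higher ones on each of the 19 autosomes, from 55.9% of calls on chromosome 19 to 63.5% on chromosome 16. The mean difference per autosome lay between -0.707 points on chromosome 16 and -0.297 on chromosome 19, and it was -1.01 on chromosome X, as averaged from the authors' deposited table. Cytosines in sparse surroundings, with at most 4 listed cytosines within 100 bp on either side, themselves included, had a mean of -0.610 points, as averaged from the authors' deposited table. The mean was -0.662 at 5 to 10 listed cytosines, where the called share was highest at 6.19%, then -0.504 at 11 to 20 and -0.236 at 21 or more, as averaged from the authors' deposited table. At 1078332 CpGs both strands were listed, and their differences correlated at r = 0.382 across CpGs, which are not independent replicates. Of called cytosines with the other strand listed, 82.9% had the same sign there and 33.5% were called there as well. The median difference of these called cytosines was -19.4 points for lower and 18.8 for higher ones, against -9.45 and 9.01 on their other strand, in the authors' deposited table.

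In 1 kb windows, lower calls outnumbered higher ones, as they also did when the same cytosine calls were shuffled. The largest fall was in a window on chromosome 16 from 18626001 to 18627000 inside Septin5, a gene for a GTP-binding septin. There 80 of 99 listed cytosines were lower and none higher, with a mean difference of -44.4 points over cytosines of the authors' deposited table. The called positions ran from 18626334 to 18626747, and the 150 other cytosines listed within Septin5 averaged 0.526 points with 3 called in the authors' deposited table. Expression of Septin5, listed as Sept5, had a log2 fold change of 0.20 (adjusted p 0.636) and the overlapping platelet glycoprotein gene Gp1bb one of 1.10 (adjusted p 0.0204) in the authors' deposited table. How reads were split between these overlapping genes is uncertain.

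Other windows with the largest falls lay in 8430419K02Rik near the homeobox gene Meis1 (-36.0 points over 5 cytosines) and in Tmem132d (-32.5 over 8), averaged from the authors' deposited table. Falls were also in Hhipl1 (-29.8 over 39) and Trub1 (-28.1 over 14), averaged from the authors' deposited table. Another 3, on chromosomes 18, 3 and 8, lay over 5000 bp from protein-coding and long non-coding RNA genes, the only classes searched. The largest rise was on an unplaced contig (38.1 points over 8 cytosines), averaged from the authors' deposited table. Of the 8 largest, those inside genes were in Ephb1, an ephrin receptor gene (35.1 points over 6 cytosines), and the monocarboxylate transporter gene Slc16a7 (30.1 over 8). Further ones were in 4930424E08Rik (29.7 over 6) and in Bcor, an X-linked corepressor gene (28.0 over 14), averaged from the authors' deposited table. The rest of the 8 were near Gm10556 on chromosome 18 and, as far from genes of these classes, on chromosomes 6 and 5. The latter rose by 32.5 and 30.7 points, each over 10 cytosines, averaged from the authors' deposited table. Of these 16 windows, 10 had fewer than 10 listed cytosines. In all, 2989 of 125698 windows were lower and 1342 higher. Scattering single cytosines at random gave on average 662 and 187 such windows in 100 shuffles, and moving both strands of a CpG together gave 1508 and 600.2, at most 1600 and 663. Lower windows outnumbered higher ones in both shuffles too, so the excess among windows adds nothing to that among cytosines. Both keep every called cytosine with its sign, so they show how far calls cluster, not the windows expected without any change. Neither keeps the dependence of neighbouring CpGs that share reads, so both understate clustering from shared reads. With calls at 50% or more of the cytosines required, 374 were lower and 151 higher.

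**Figure D2:**
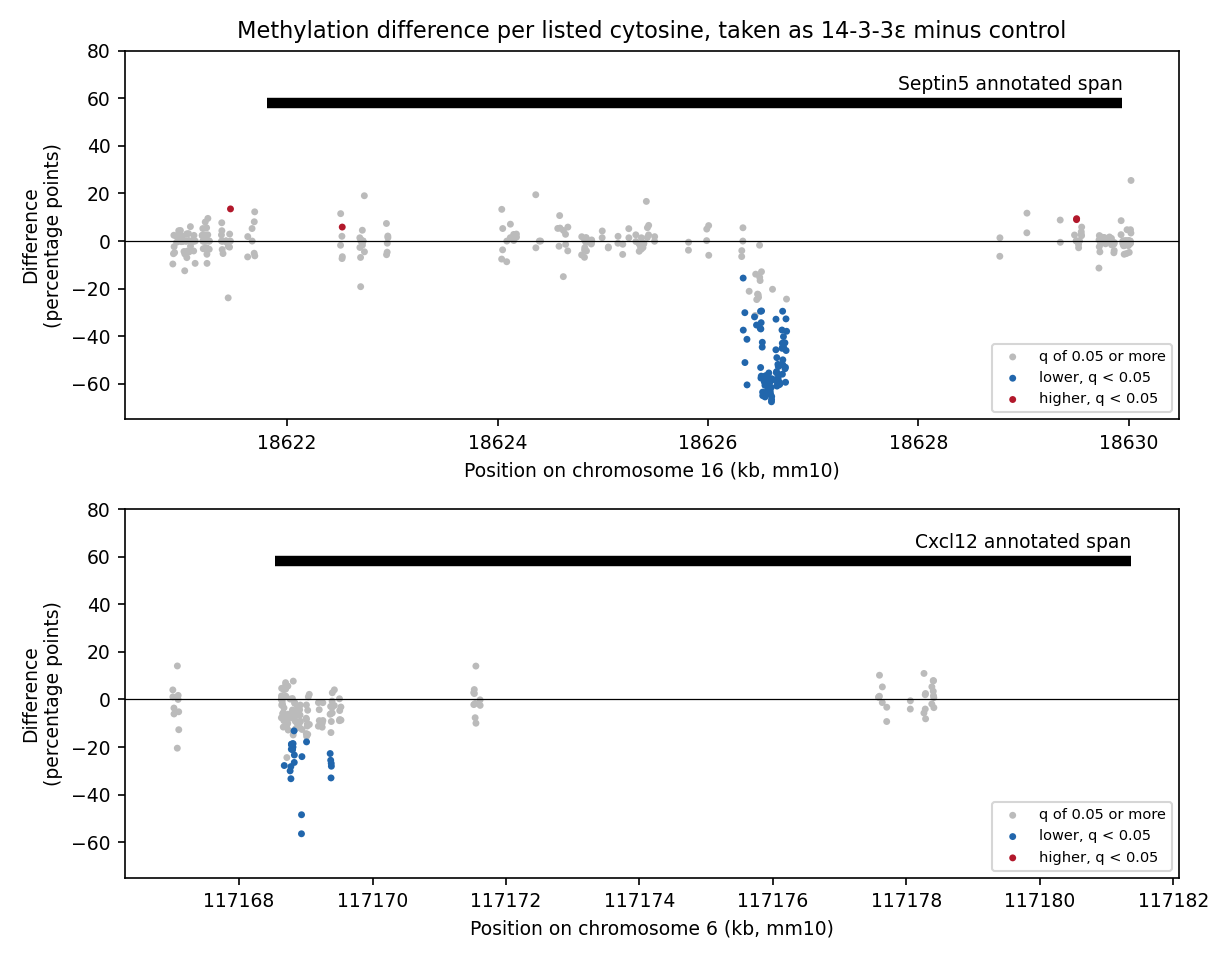
Difference in methylation (vertical axis, percentage points, taken as 14-3-3ε minus control) of each listed cytosine along Septin5 and Cxcl12 (horizontal axis, kb in mm10), with the annotated span of each gene as a black bar. Blue points are lower and red points higher at q under 0.05; 80 cytosines of Septin5 between 18626334 and 18626747 and 23 at the lower-coordinate end of Cxcl12 are lower.

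At gene ends, 273 of 14435 protein-coding genes with enough cytosines were lower and 164 higher. On average, 100 shuffles of single cytosines gave 73.1 and 19.2, and moving both strands of a CpG together gave 151 and 54.7. These shuffles have the same limits as those of windows, and lower gene ends outnumbered higher ones in them too. With calls at 50% or more of the cytosines required, 11 and 4 were left. A cytosine without a call need not be unchanged, since coverage is unknown. The largest falls were at Rgcc, a regulator of the cell cycle (-22.7 points over 36 cytosines, 17 lower), at the secreted ligand gene Wnt7a (-21.8 over 9) and at Cyba, a subunit of NADPH oxidase (-18.1 over 56, 29 lower), averaged from the authors' deposited table. They were followed by Pxdc1 (-16.5), Tpd52 (-16.4), Dusp27 (-16.3), Mall (-15.5) and Bnc1 (-15.5 over 171 cytosines, 66 lower), averaged from the authors' deposited table. The largest rises were at Ccdc65 (21.9 points over 14 cytosines), the glial-factor receptor gene Gfra2 (18.1 over 68, 21 higher), Lmcd1 (15.6) and Cfap20dc (15.1), averaged from the authors' deposited table. Tspan31 (14.8), the shared end of Tspan10 and Pde6g (14.7) and Igdcc4 (13.6) came next, averaged from the authors' deposited table.

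No list passed Fisher's exact test for called gene ends, with adjusted p of at least 0.792 in either direction. Within the lists, lower gene ends were those of Cxcl12, Zbtb4, Mcam, Itgb8, Stat2, Pax3, Pax6, Barx1, Hoxc6, Fos and Egr3. Higher ones were those of Cx3cl1, the epithelial 14-3-3 gene Sfn, Mbd1, Piwil1, Stag3, Psmb8, Hoxb6, Cidec, Col2a1 and Map2. The homeobox genes Pax6 and Hoxb6 stood at -7.79 and 12.2 points over 24 and 40 cytosines of the authors' deposited table. The gene end of Ywhae averaged 0.249 points over 159 cytosines with 1 called, and no more than 2 cytosines were listed at that of Dnmt1, in the authors' deposited table. The Tet1 end held 22 lower and 1 higher call of 76 and so was not called, with a mean of -5.18 points in the authors' deposited table.

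Methylation at gene ends and expression of the same gene were then compared, in the assumed direction of both. Genes with a lower gene end had risen more often: 19 of 130 (14.6%) against 5.79% of 9550 genes without a call, an odds ratio of 2.78 (Fisher exact p = 0.000215, two-sided, adjusted p 0.000858 over 4 tests). Among genes with a higher gene end 10 of 90 had risen (11.1%), an odds ratio of 2.03 that did not pass after adjustment (Fisher exact p = 0.0408, adjusted p 0.0817). Rises at lower and at higher gene ends were not shown to differ (odds ratio 1.37, Fisher exact p = 0.545). Cxcl12, with the largest rise in expression, was among them: its end at the lower coordinate, from 117167535 to 117169535 on chromosome 6, averaged -9.58 points over 118 cytosines, 23 of them lower, in the authors' deposited table. Kank3, a gene for an ankyrin repeat protein, combined -9.40 points with a log2 fold change of 2.23, and Rgcc -22.7 points with 1.84, in the authors' deposited table. Such pairs fix at most the relative sign of the assays, since reversing both leaves the relation as it is.

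The interferon transcription factor gene Stat2, the immediate early genes Egr3 and Fos, Rnf150 and Rab36 also had a lower end and a rise, with log2 fold changes of 1.22, 1.49, 1.52, 1.16 and 1.72 in the authors' deposited table. So did Tpd52 (-16.4 points, log2 fold change 1.85), Bnc1 (-15.5, 1.06), Zbtb4 (-5.31, 0.73) and Hoxc6 (-2.95, 0.77) in the authors' deposited table. Some of these ends changed little on average, with means of -1.43 points for Egr3 and -2.12 for Fos in the authors' deposited table. With calls at 25% or more of the cytosines required, the ends of Rgcc, Tpd52 and Bnc1 stayed called, while those of Cxcl12, Kank3, Stat2, Egr3, Fos, Rnf150, Rab36, Zbtb4 and Hoxc6 did not. The reverse, a higher end and a fall, was seen in 4 genes, among them the microtubule gene Map2 (8.03 points, log2 fold change -1.36), Rgs17 (10.8, -1.32) and Zfp365 (2.40, -0.87) in the authors' deposited table. Both values were higher in 10 genes, among them Tspan31, the chemokine gene Cx3cl1 (12.3 points, log2 fold change 0.97), the collagen gene Col27a1 (13.1, 1.01) and Setbp1 (9.30, 1.11) in the authors' deposited table. Slc29a3, Zmiz1, Nynrin and Cyp39a1 were the other named ones. Both values were lower in Slc6a15 and Rasa4. Among the 35 genes called in both assays, Fisher's exact test of direction in one against direction in the other gave p = 0.191 (two-sided, odds ratio 3.8), so that a dependence was not shown.

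Across 9770 genes with both values, the gene-end difference and the log2 fold change had a Spearman correlation of -0.043 and a Pearson correlation of -0.0794 (permutation p = 3e-05 for the rank correlation, adjusted p 0.00024 over 8 sets). Genes are not independent replicates, and the size leaves nearly all of the variation in expression unrelated to these windows. Over the 220 genes with a called gene end the Spearman correlation was -0.273 (permutation p = 0.0002). Of the 24 genes with the largest changes in expression, Cxcl12 alone had a called gene end, and 10 had no listed cytosine there, among them Agtr2, Col3a1 and Prl2c2. Ahr, which fell, averaged 6.60 points over 103 cytosines with 4 higher, too few for a call, in the authors' deposited table.

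**Figure D3:**
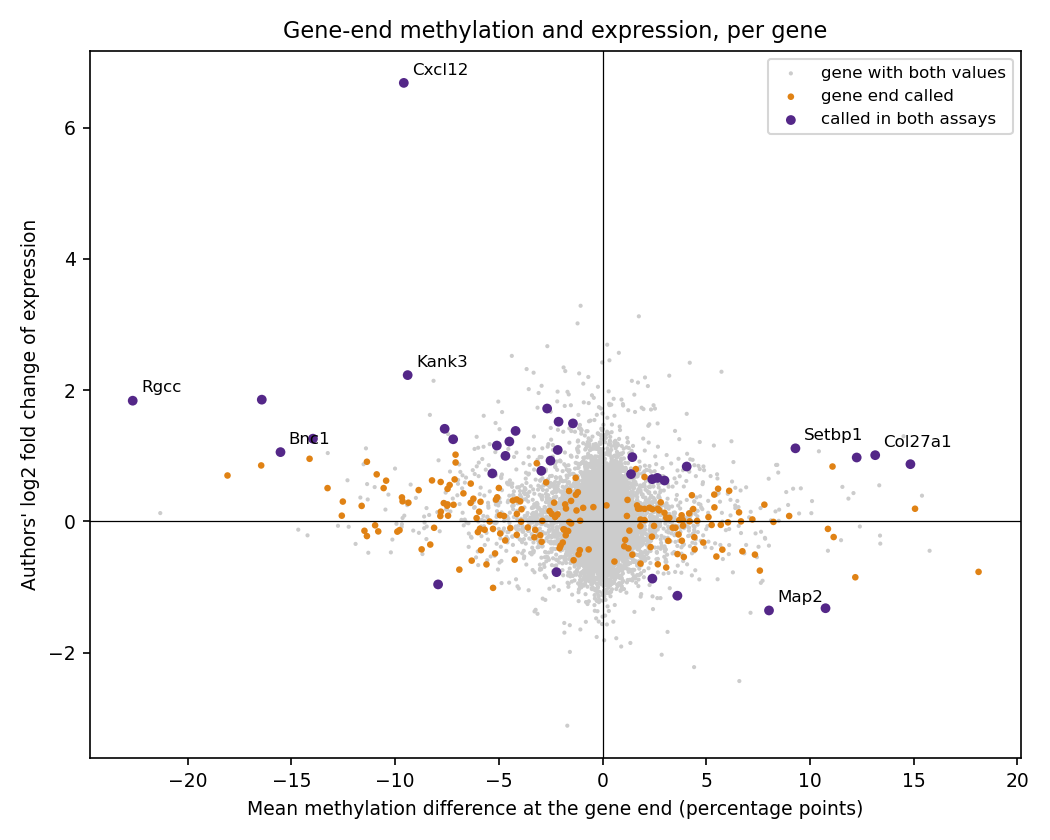
Mean methylation difference at the gene end (horizontal axis, percentage points) against the authors' log2 fold change of expression (vertical axis) for 9770 genes. Orange points are genes with a called gene end and purple points the 35 genes called in both assays; 19 of the purple points lie at lower methylation and higher expression, Cxcl12 highest.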

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

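Settings on calls at 25% or 50% of cytosines, q under 0.01, no filter on low counts, chromosome centring and 3 classes of mean count were chosen after seeing the data. Fisher's exact test of lists was planned beside cameraPR and only its use here as an alternative was added. At an adjusted p under 0.01, 413 genes were higher and 252 lower. At an adjusted p under 0.05 and at least a 2-fold change, 331 were higher and 122 lower. The 6 list calls held in a rank-sum test, at a mean count of 50 or more and with chromosome centring. In Fisher's exact test of called members of either direction the imprinted list did not pass (adjusted p 0.396), the other 5 did, and the Ras feedback (4.53e-05) and chemokine lists (0.0212) passed as well. The contractile list passed a rank-sum test (adjusted p 0.0245), and the DNA methylation and Ras feedback lists, not called in either test, took the other sign there (0.991 for both), with medians near 0. Called cytosines fell to 12122 higher and 19607 lower at 25 points or more, and to 23172 and 35274 at q under 0.01. Windows higher and lower numbered 704 and 1649 with calls at 25% of cytosines, 151 and 374 at 50%, 668 and 1437 at q under 0.01, and 10 and 15 at 25 points. Gene ends numbered 36 and 74 at 25%, 4 and 11 at 50%, 94 and 158 at q under 0.01, and 0 and 0 at 25 points. These settings are stricter by construction, and lower calls stayed more frequent than higher ones in every methylation setting that left any. Windows and gene ends share the excess of lower cytosines, so they do not show the direction anew.

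The odds ratio for a rise at lower gene ends was 0 at 50%, where 6 gene ends were left, and lay between 2.67 and 3.07 in the other settings. Spearman's rho stayed below 0 in all, between -0.273 and -0.0348. Of 82 named genes, 72 stayed called or uncalled as before at an adjusted p under 0.01. Of 51 named gene ends, 21 kept their call at 25% and 27 at q under 0.01. Of 16 named windows, 15 kept it at 25%, but 6 had 10 or more cytosines. No paired analysis was possible because the compared groups are different clones and the tables hold no values per library. For the same reason coverage limits, pooled tests, other count tools, read weighting and leaving out each clone were not run, and depth remains unknown.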

Other observations

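The tests of mitochondrial cytosines, of sparse surroundings, of windows counted once, of the other strand, of both parts of each chromosome and of random pairings were chosen after their results had been seen. The classes of mean count and chromosome centring were also added after seeing the data, with what the classes would show written before their result. The tests without called genes and of the protocadherin cluster were set out before their results, on patterns found in these data. Directions here rest on the assumed sign of both tables.

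Of the protocadherin beta genes, neuronal adhesion genes in a row on chromosome 18 from 37264998 to 37521419, 8 of 19 tested were called higher, none was lower and the rest did not pass, and log2 fold changes ran from 0.17 to 1.01 in the authors' deposited table, the highest in Pcdhb22. These genes are related copies in 1 family, whether they shared reads was not measured, and they were named after their values were seen. In the Hoxd cluster 3 of 4 tested genes rose, in the Hoxc cluster 2 of 3 and in the Hoxa cluster 2 of 7, while in the Hoxb cluster none of 4 was called and the median was -0.14 in the authors' deposited table. The Hoxb cluster, on chromosome 11 from 96194316 to 96368254, averaged -2.55 points over 1482 cytosines, with 98 lower and 53 higher, in the authors' deposited table. The means were 0.512 points in the Hoxd cluster, -0.382 in the Hoxc cluster and -0.457 in the Hoxa cluster, averaged from the authors' deposited table, and no relation to expression was tested across these clusters. The span from Dlk1 to Mirg, with 4 of 5 genes risen, averaged -0.634 points over 523 cytosines, 15 lower and 4 higher, in the authors' deposited table.

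A candidate explanation for the higher protocadherin beta genes is lower methylation of their cluster. Of the 242 cytosines listed in the cluster, 11 were called lower and 1 higher. The cluster averaged -0.988 points over them in the authors' deposited table, and 24.3% of 10000 runs of as many neighbouring cytosines had a lower mean. The value lies below the median of the runs (-0.350) but well inside their range, so this hypothesis is left open.

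More called cytosines were lower than higher. Less complete conversion of unmethylated cytosines in control clones would put mitochondrial cytosines below 0 as well, yet these averaged 0.394 points (standard error 0.165 over 252 cytosines, which share reads) in the authors' deposited table. A few crowded regions are argued against by windows counted once. Of 48075 windows with at least 1 call and all calls in 1 direction, 60.6% were lower, without the minima of the calling rule. Read sampling as the source of most calls is argued against by the other strand, which had the same sign for 82.9% of called cytosines. That share was alike for higher (82.7%) and lower calls (83.1%), so by itself it does not explain the excess of lower ones. Differences were smaller on the other strand, so sampling may still enlarge the called differences. Conversion of methylated cytosines in 14-3-3ε clones stays open: the mean in sparse surroundings was below 0 (-0.610 points), but the authors' deposited table holds no methylation levels to decide it. Drift between clones and an effect of 14-3-3ε both stay open and untested, since the table holds no values per clone.

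Genes of a chromosome shifted together in expression, with medians of log2 fold change from -0.19 on chromosome 8 to 0.19 on chromosome 10 in the authors' deposited table. Without called genes the medians still spanned 0.29, against at most 0.13 in 100 shuffles, so the spread was not confined to called genes. A median over many genes barely responds to a few strongly changed ones, so this step could hardly have pointed to them. A change in the copy number of whole chromosomes in some clones may account for the shifts: over 20 chromosomes, the medians of genes below and above the middle had a Spearman correlation of 0.786 (Pearson 0.905; permutation p = 6e-05), and 0.707 without chromosomes 8 and 10 (permutation p = 0.00138). Broad regulation would give the same medians and was not tested. Centring each chromosome left all 6 cameraPR list calls in place.

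Lower gene-end methylation went with higher expression at a rank correlation of -0.043, outside nearly all random pairings of genes, whose central 95% lay between -0.0199 and 0.0198. Pairings were drawn over the whole genome although genes of a chromosome shifted together. This range may therefore be too narrow and the permutation p-values too small. A shared dependence on expression level is argued against by 3 equal classes of mean count, in which the correlation was -0.0503, -0.0348 and -0.0444 from lowest to highest, though the middle one passed narrowly (permutation p = 0.0486). Cause and consequence cannot be read from these tables, and no biological explanation was tested.

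Among stretches of 1 Mb with at least 200 listed cytosines, 85.0% of 2196 had a mean difference below 0. The lowest lay on chromosome 2 from 139 to 140 Mb (-6.10 points, 50 cytosines lower and 3 higher) and on chromosome 14 from 116 to 117 Mb (-5.96, 38 lower and none higher) in the authors' deposited table. The highest lay on chromosome 2 from 98 to 99 Mb (4.16 points, 60 higher and 13 lower) in the authors' deposited table. Next came chromosome 9 from 3 to 4 Mb (3.47 points), with mixed calls, 40 higher and 26 lower, in the authors' deposited table. How uniquely reads mapped in these stretches was not measured.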
